A study of Arabidopsis thaliana with 12 samples.

How the data were processed

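The series holds 12 samples of total RNA from wild-type Arabidopsis thaliana, ecotype C24, 6 from plants under PSI light and 6 from plants under PSII light with DCMU, each with a number from 1 to 6 in its title. The deposited table gives 1 intensity on a linear scale per array feature and sample. How the authors made these intensities (array type, scanner, background correction, scaling) is not given in the sources used here. The deposited values run from 0 to 100, none is negative or missing, 13 values lie at 100, and 108 to 144 values per sample are exactly 0. Column means lay within 3.25% and column medians within 11.9% of their averages. By a rule set before the data were examined, a table whose column means or medians lie within 10% of their average counted as normalized and was kept as deposited. The scale of the intensities, the background level and the meaning of an exact 0 stay unknown. An array feature listed at 0 may be a failed measurement, and 45 features are listed at 0 in all 12 samples.

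Values below the 1st percentile of the positive intensities (0.0431), including 0, were set to it, which concerned 4.74% of all values, and log2 was taken. Folds of dim features therefore depend on this floor. No column belonged to another sample. Features were named through the platform's gene table, which can be old. It gave exactly 1 gene for 692 features, several for 870 and none for 1877. Of the 692, 690 were matched by gene identifier to the reference gene table of the assembly TAIR10.1, from which locus names and symbols were taken. Short names of some photosynthesis genes follow common use for their locus. A feature can detect related genes, and the probe sequences were not used here, so members of gene families such as LHCB1.5, the histone H3 genes and the pentatricopeptide repeat genes are uncertain to that degree. No coordinates are given, since no genome build is named with the table.

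Whether sample numbers mark technical pairs was checked on deviations from the group means, as planned. Partners 1 and 2, 3 and 4, and 5 and 6 of a group correlated at 0.38 to 0.66 and other samples of a group at -0.51 to -0.18, and all 12 samples correlated best with their partner. Each pair was therefore averaged on the log2 scale to 1 replicate, named replicate 1, 2 or 3, which left 3 replicates per group. The pair numbers also pair the replicates across the groups. Deviations of same-numbered replicates correlated at 0.29 to 0.36, those of other numbers at -0.33 to 0, and all 12 samples correlated best with their own number in the other group. This pairing comes from the data and the numbers in the titles, and no label says what a number stands for.

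The comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (Python 3.11.15 and matplotlib 3.10.9 for figures), with 1 coefficient for PSII light with DCMU against PSI light, two-sided, no block, and Benjamini-Hochberg adjustment over 3439 features at 0.05. An exact permutation test of 3 against 3 replicates cannot give a p below 0.1. Log2 changes are given with the moderated standard error, and intensities as mean ± SD over 3 replicates. For these intensities the samples of a pair were averaged on the linear scale without the floor, unlike in the fit. The fit was tested on simulated data with the real features' levels and spread and 200 changed features. It recovered 0% of changes of 0.5, 59% of changes of 1 (5 false calls) and 91.5% of changes of 2 (19 false calls), made 0 calls with no change, and treating the 12 samples as separate made 88 false calls there. At a change of 2 the 19 were among 202 calls, a larger share than the threshold of 0.05 aims at. Noise was drawn independently for each feature, and more features were called in the data, so these rates need not hold for the data.

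Before the data were examined, 22 gene lists were fixed (photosynthesis, plastid metabolism and gene expression, stress, redox readouts, other tissues). Of their 393 distinct genes 22 were measured by a named feature. Lists with no measured member numbered 11, the redox readouts, the plastid-encoded genes and the markers of non-green tissue among them, and 2 lists had the 3 members needed for a set test. The lists of single measured genes appear under the gene. Another 10 lists were written after the gene names of the array were read and a few lines of its values had been viewed, but before any change was computed. They are not independent of the array's content. Sets were tested with camera at a preset correlation of 0.01, adjusted over the 2 or the 10 lists, and again with an estimated correlation. No set passed with either. Also fixed was the rule for named genes: the 12 largest rises and 12 largest falls among called features with 1 gene whose groups do not overlap, in each list the 2 smallest p and the largest change, and all measured redox readouts, of which there were 0. It gave 57 genes. The other measured list members and the gene with 2 features, 55 features in all, were put through the same alternatives after their values were seen, so that any of them could be named.

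The alternatives were quantile normalization, median centring, division by the mean, the pair number as a block, 12 separate samples, pairs as a random block, samples 1 to 3 against 4 to 6 as a block, the dimmest 25% left out, a floor at the 10th percentile (0.161), that value as a pseudocount, eBayes with trend and robust settings, array weights, stricter thresholds, fry and leaving out each replicate. Added after the data were seen were the removal of a loess trend with brightness (span 0.3), of the feature's place within runs of 288 feature numbers (the mean of each step of 6 numbers and of each position in a step, taken from every replicate), of both, features never at the floor only, a block with pairs as random, and an exact permutation test over 12 samples. Feature numbers are the identifiers of the deposited table and run up to 4607. That they follow the layout of the array is an assumption.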

Results

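Transcript levels were measured with an expression array in wild-type Arabidopsis thaliana of the ecotype C24. Plants kept under light that mainly excites photosystem I (PSI light) were compared with plants kept under light that mainly excites photosystem II and treated with DCMU (PSII light with DCMU). Photosystem II passes electrons through the plastoquinone pool to photosystem I. DCMU is a herbicide that blocks the transfer from photosystem II to plastoquinone, and PSI light draws electrons out of the same pool. No sample had PSII light without DCMU or PSI light with DCMU, so no change can be assigned to the light or to DCMU alone. Each group held 6 samples of total RNA, and 1 intensity was given for each of 3439 array features in each sample. The median intensity of a sample lay between 0.542 and 0.584 under PSI light and between 0.632 and 0.688 under PSII light with DCMU. Within a group, samples 1 and 2, 3 and 4, and 5 and 6 were nearly alike (Spearman correlation across features 0.98 to 0.99), while other samples of a group correlated at 0.92 to 0.94 under PSI light and at 0.95 to 0.97 under PSII light with DCMU. Each such pair was averaged to 1 replicate, so n = 3 per group in what follows. The number of arrays limits the precision of every value. The labels do not say whether samples came from separate plants, so the p-values measure the spread between these samples, which may be technical. Of the 3439 features, 692 were paired with exactly 1 gene, and only these are named.

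**Figure D1:**
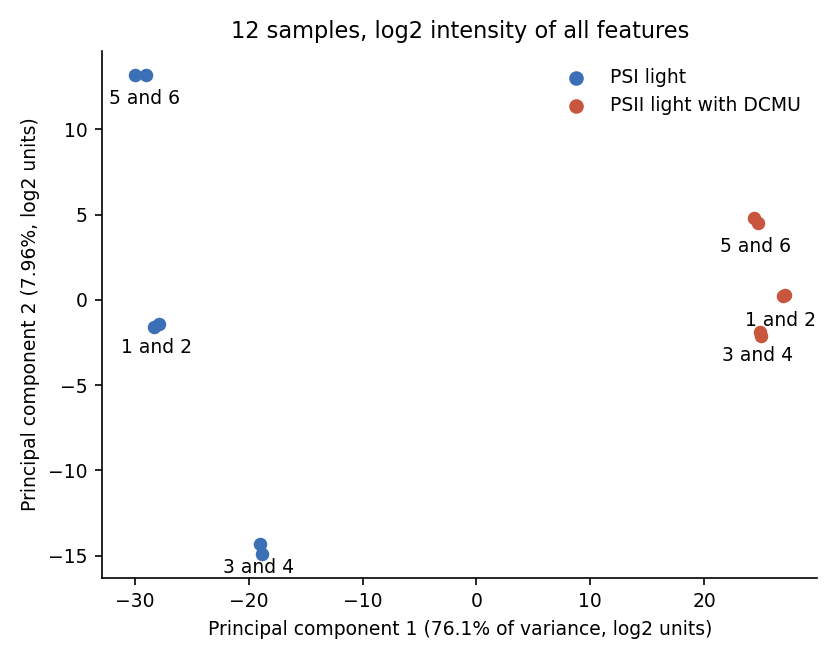
Each point is 1 of the 12 samples placed by the first and second principal components of the log2 intensities, coloured by group and labelled with the sample numbers of each pair. The first component held 76.1% of the variance and separated the groups, and the second, with 7.96%, spread the pairs within a group.

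Under PSII light with DCMU, PYG7, which encodes a thylakoid protein needed for photosystem I to accumulate, had 5.57 times the intensity it had under PSI light (0.166 ± 0.0166 under PSI light, 0.923 ± 0.0349 under PSII light with DCMU, SD, n = 3). The gene of the NADP-dependent malate dehydrogenase of the chloroplast (NADP-MDH) rose 4.19-fold, and the Calvin-Benson enzymes phosphoribulokinase (PRK) and sedoheptulose bisphosphatase (SBPASE) rose 1.77-fold and 1.54-fold. These 3 calls had limits, given with their group below: that of NADP-MDH ended with the pair number as a block (adjusted p = 0.0521) and without any 1 of 4 of the 6 replicates (0.0696 to 0.0793), and those of PRK and SBPASE ended under 2 other scalings and without certain replicates. PSB27, which acts in the assembly and repair of photosystem II, fell from 3.68 ± 0.455 to 1.62 ± 0.247 (SD, n = 3). Of 17 measured genes for pentatricopeptide repeat proteins, most of which act on RNA in plastids and mitochondria, 8 rose and 2 fell. These changes sat within a difference that reached 1667 of the 3439 features, or 48.5%, past an adjusted p of 0.05 (limma, Benjamini-Hochberg), 909 higher and 758 lower under PSII light with DCMU. At an unadjusted p of 0.05, 1063 features were higher and 885 lower. The replicates of the 2 groups did not overlap in 2088 features, or 60.7% of all, where chance gives 10%. Of the called features, 521 were at least 2-fold higher and 147 at least 2-fold lower. The share of higher calls was 54.5% with the intensities as deposited, 41.6% after quantile normalization and 39.6% with each array centred on its median, so the balance between rises and falls depended on the scaling. Centring moved the median log2 change of all features from 0.04 to -0.09. Among the 692 named features, 193 rose and 145 fell.

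The size of a change also followed how bright a feature was and where it stood in the order of feature numbers. The median log2 change was 0 in the dimmest of 10 nearly equal classes of brightness (mean intensity 0.0797), 0.64 in the second dimmest and -0.44 in the brightest. Within runs of 288 consecutive feature numbers, the median log2 change was -0.31 at places 1 to 96, 0.42 at places 97 to 192 and 0.16 at places 193 to 288. Calls split accordingly, with 89 higher and 449 lower at places 1 to 96 and 463 higher and 102 lower at places 97 to 192. Place explained 32.7% of the variance of the log2 changes between the groups (adjusted for the number of places), against at most 1.66% in 100 random orders. It also explained 16.7% to 36.0% of the variance of differences between replicates of the same group. With place taken out of every replicate, a correction chosen after this pattern was seen, 1872 features were called, and 1081 of the 1667 kept their call and direction. The correction has a fault of its own, since it called 133 of the 141 features that lay under the floor in all 12 samples, where nothing was measured. Features above the floor were corrected in the same way, so a call gained or lost only with place taken out is uncertain. Its values for features under the floor are given below only to show this fault. For called genes named with a change, the value with place taken out is given where the correction ended the call or moved the change by more than 1.5 times, and values with brightness taken out as well are given for some genes only. For genes that did not pass, mainly the alternatives in which they passed are given.

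**Figure D2:**
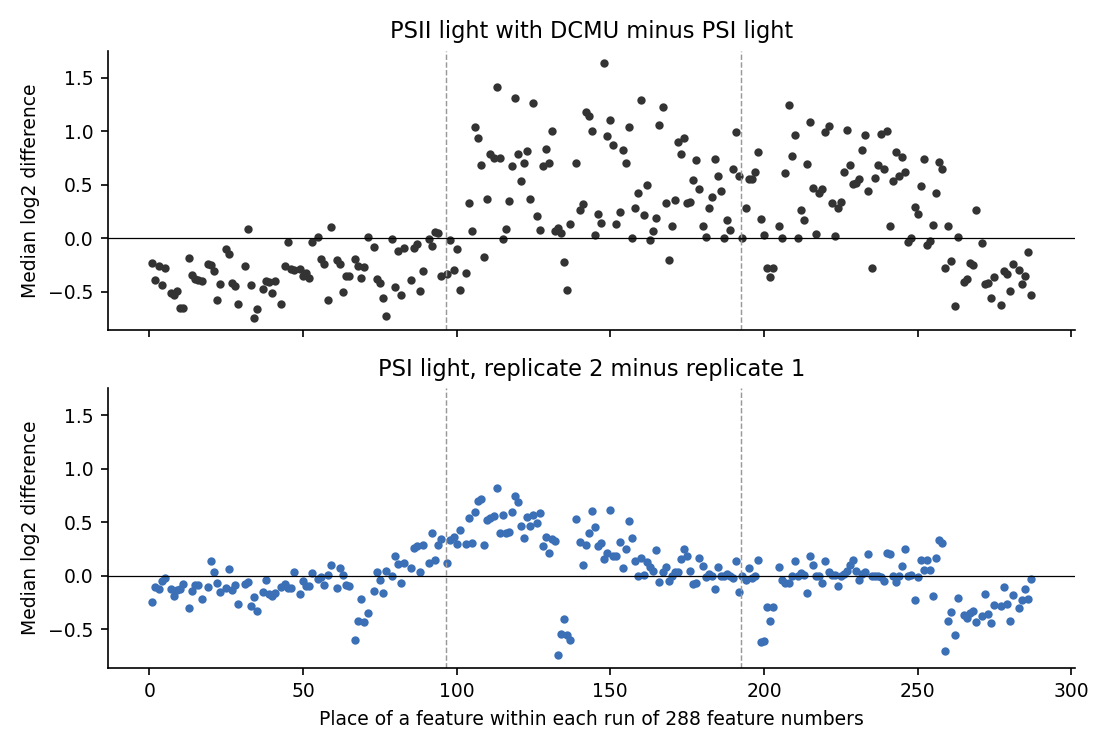
Median log2 difference of the features at each place within runs of 288 feature numbers, for the 264 places that hold 5 or more features, between the groups (top) and between replicates 2 and 1 of PSI light (bottom). Dashed lines part places 1 to 96, 97 to 192 and 193 to 288, whose median changes between the groups were -0.31, 0.42 and 0.16, and the differences between replicates of PSI light varied with place too.

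The named genes that rose most were AT5G46390, a carboxyl-terminal processing peptidase of family S41, by 3.91 ± 0.142 (log2, SE, n = 3; adjusted p = 0.000321), AT3G25680 by 3.53 ± 0.15 (adjusted p = 0.000338) and AT3G56330, a tRNA dimethylguanosine methyltransferase, by 3.34 ± 0.193 (adjusted p = 0.000644). The kinesin gene AT4G14330 rose by 3.18 ± 0.327 and the F-box gene AT2G23160 by 3 ± 0.547. The others of the 12 with the largest rises were AT5G65490 (2.80), the protein kinase gene AT5G40030 (2.73), AT2G30100 (2.70), AT1G75260 (2.52), PYG7 (2.48 ± 0.087), ATATH8 (2.40) and AT5G02050 (2.39), with adjusted p of 0.000321 to 0.0109 over the 12. All 12 were dim under PSI light, with mean intensities of 0.0479 to 0.243, and reached 0.512 to 1.54 under PSII light with DCMU. Because the floor under the intensities was 0.0431, the fold of the dimmest depended on how low values were treated. With a floor of 0.161, the rise of AT3G25680 was 1.92 and that of AT5G65490 was 1.67. With 0.161 as a pseudocount the 12 rises were 1.51 to 2.37, and 8 of them were smaller by more than 1.5 times: AT5G46390 (2.37), AT2G23160 (1.98), AT4G14330 (1.93), AT3G25680 (1.89), AT5G02050 (1.59), AT1G75260 (1.57), AT5G65490 (1.51) and ATATH8 (1.51). With place and brightness taken out the rise of AT4G14330 was 2.1, that of AT5G40030 1.72, that of ATATH8 1.45 and that of AT5G02050 1.36. All 12 kept their call under the 21 to 23 alternatives that gave them a value.

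The named gene that fell most was AT4G02580, for the 24 kDa subunit of mitochondrial complex I, by 1.86 ± 0.222 on the log2 scale (adjusted p = 0.00321), from 0.181 ± 0.0525 to 0.0462 ± 0.00499 (SD, n = 3), which is close to the floor. With the floor of 0.161 its change was -0.20 ± 0.177 and the call ended, because both groups then lay at or near the floor. AT5G11550 fell by 1.70 ± 0.149, AT1G03810 by 1.52 ± 0.058 and AT5G19750, of the Mpv17 and PMP22 family of membrane proteins, by 1.45 ± 0.098. AT1G03810 was among the brightest features under PSI light and went from 5.82 ± 0.116 to 2.03 ± 0.122 (SD, n = 3). Its change was -0.92 ± 0.117 with place and brightness taken out, where that of AT2G36480, given below, was -0.83 ± 0.193. The mannan synthase family gene CSLA01 fell by 1.36 ± 0.224 and the histone H3 gene AT1G09200 by 1.3 ± 0.139. The others of the 12 were AT4G35980 (-1.44), AT4G30680 (-1.37), AT4G18180 (-1.33), AT4G22490 (-1.31), AT2G36480 (-1.31) and AT2G13690 (-1.24), with adjusted p of 0.000321 to 0.0223 over the 12. The change of AT5G19750 was -2.21 ± 0.119 and that of CSLA01 -0.89 ± 0.197 with place taken out. The call of AT4G18180 ended when any single replicate except PSI replicate 3 was left out, with adjusted p of 0.0557 to 0.0737.

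**Figure D3:**
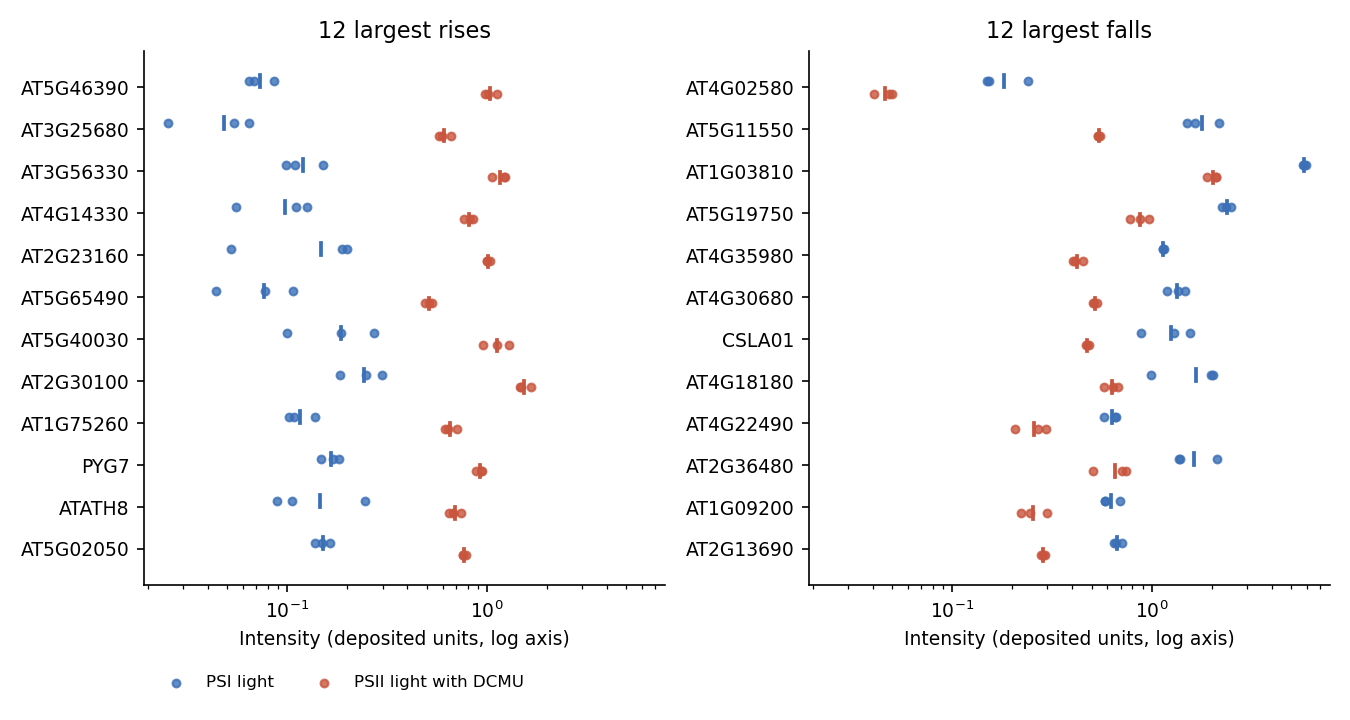
Intensity of each replicate (points, n = 3 per group, each the mean of a pair of samples) and the group mean (bars) on a log axis, for the 12 named genes with the largest rises and the 12 with the largest falls. The replicates of the groups do not overlap for any of the 24 genes, as the rule that chose them required, and the genes that rose were dim under PSI light.

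Photosystem, antenna, cytochrome b6f and NDH subunits and their assembly factors formed a group of 14 measured genes. It was listed after the array's gene names were read and a few lines of its values had been viewed, but before any change was computed, as were 9 other groups below. Lists called earlier were fixed before the gene names were read. In this group 6 genes rose, 3 fell and 5 did not pass the test (6 rose and 4 fell when adjusted over the list alone). Apart from PYG7, the genes that rose were CRR41 (1.89 ± 0.259), an assembly factor of the chloroplast NDH complex, RIQ2 (1.13 ± 0.287), which affects grana stacking, the NDH subunit genes NDHS (0.78 ± 0.135) and NDHN (0.75 ± 0.074), and PIFI (0.75 ± 0.157), which acts in chlororespiration. PSB27 fell by 1.18 ± 0.154 (by 0.61 ± 0.154 with place and brightness taken out), LPA19, another photosystem II assembly factor, by 0.88 ± 0.119 and RBD1, a thylakoid rubredoxin, by 0.59 ± 0.069. In this and the next paragraphs, list members outside the rule for named genes were chosen for naming after their values were seen, here CRR41, RIQ2, NDHS, PIFI, LPA19, RBD1, PSBW and CCB3. The photosystem I subunit gene PSAN (0.13, adjusted p = 0.252), the photosystem II subunit genes PSBW (0.19, adjusted p = 0.235) and PSBY (0.40, adjusted p = 0.213) and the antenna gene LHCB1.5 (-0.34, adjusted p = 0.0651) did not pass, and CCB3 lay under the floor in both groups. No shift of the group as a whole against the other features was detected (limma camera, adjusted p = 0.673, and adjusted p = 0.774 with an estimated correlation). In the shorter, earlier list of photosystem II core genes, 3 of 13 were measured, 0 rose and PSB27 fell, also when adjusted over the list alone. Its median change was 0.19 while its mean was -0.20 and the set test pointed down (adjusted p = 0.776). With the pair number as a block, PSBY and LHCB1.5 passed the test and RIQ2 did not. Place taken out brought NDHN from 0.75 ± 0.074 to 0.02 ± 0.14 and PIFI from 0.75 ± 0.157 to -0.03 ± 0.116, and both lost their calls with changes smaller than their standard errors. It brought CRR41 to 1.22 ± 0.165, RIQ2 to 0.71 ± 0.212, LPA19 to -0.46 ± 0.119 and RBD1 to -0.34 ± 0.11, all still past the threshold, though RBD1 did not pass with brightness taken out as well (-0.26 ± 0.11), and PSAN (0.50 ± 0.123), PSBY (0.76 ± 0.181) and PSBW (0.65 ± 0.137) passed. After quantile normalization PIFI stood at 0.09 ± 0.118 and RIQ2 at 0.53 ± 0.188, neither past the threshold, and PSAN passed (0.45 ± 0.096). LHCB1.5 passed with each array centred on its median (-0.56 ± 0.099) and stood at 0.12 ± 0.132 with place taken out. The call of RIQ2 ended without PSI replicate 1 or any PSII_DCMU replicate (adjusted p = 0.0597 to 0.0888) and that of PIFI without PSII_DCMU replicate 1 or 2 (0.0548 and 0.0503). Over its 22 alternatives the change of RIQ2 was as low as 0.45 and its adjusted p (limma) as high as 0.249.

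Genes of stromal carbon reduction and its thioredoxin control moved both ways. Of 5 measured genes, NADP-MDH (2.07 ± 0.505, adjusted p = 0.0253), PRK (0.82 ± 0.177, adjusted p = 0.0177) and SBPASE (0.63 ± 0.156, adjusted p = 0.0268) rose, and FTRB, the catalytic subunit of the ferredoxin-thioredoxin reductase that activates these enzymes in the light, fell by 0.53 ± 0.063 (adjusted p = 0.00321). NTRC, an NADPH-dependent thioredoxin reductase, did not pass (-0.09, adjusted p = 0.852). Adjusted over the list alone, 3 rose and 1 fell, and the set test gave an adjusted p of 0.747 (0.774 with an estimated correlation). PRK and SBPASE were the 2 measured members of the earlier Calvin-Benson list, and both rose also when adjusted over the list alone. PRXIIE, a chloroplast peroxiredoxin that removes peroxides and the 1 measured gene of the antioxidant list, rose by 0.88 ± 0.241 (adjusted p = 0.0355). PRK and SBPASE lost their calls after quantile normalization (0.64 ± 0.234 and 0.45 ± 0.176) and with each array centred on its median (0.60 ± 0.216 and 0.41 ± 0.182). Place taken out brought PRXIIE to 0.11 ± 0.166, which ended its call, and PRK to 1.25 ± 0.20, and with the pair number as a block NADP-MDH and PRXIIE did not pass (adjusted p = 0.0521 and 0.0806, within the ranges of 0.000314 to 0.0793 and 0.000751 to 0.587 over the alternatives). Leaving out 1 replicate ended the call of PRK without PSI replicate 1 or PSII_DCMU replicate 3 (adjusted p = 0.0545 and 0.0604) and that of SBPASE without PSI replicate 3 or PSII_DCMU replicate 2 or 3 (0.0527 to 0.0864). NADP-MDH did not pass without PSI replicate 3 or any PSII_DCMU replicate (0.0696 to 0.0793), nor did PRXIIE without PSI replicate 1 or any PSII_DCMU replicate (0.0513 to 0.105).

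Genes for organelle gene expression made up 3 groups. Of the 17 genes for pentatricopeptide repeat proteins, 8 rose, 2 fell and 7 did not pass, and adjusted over the list alone 12 rose and 2 fell. Their median change was 0.68, with AT3G22150 at 1.88 ± 0.388 and AT2G17670 at 1.27 ± 0.143 among those that rose, while AT4G14050 fell by 1.03 ± 0.105. The group's shift against other features had p = 0.0251 and an adjusted p of 0.251 over the 10 groups listed in this way (limma camera), and p = 0.108, adjusted p = 0.774, with an estimated correlation. The median was positive under each scaling, and lay between 0.46 and 0.82 over 23 alternatives. With place taken out it was 0.51, and 8 genes rose and 3 fell, of which 5 and 1 were among those called before, so part of the genes changed. AT3G22150 and AT2G17670 then stood at 1.19 ± 0.322 and 0.65 ± 0.172, and AT1G79080, the other gene that fell (-0.36 ± 0.099), at -0.06 ± 0.12, its call ended. AT5G15280 went from 1.4 ± 0.275 to 0.65 ± 0.251, AT3G51320 from 0.60 ± 0.139 to 0.09 ± 0.136 and CRR21 from 0.66 ± 0.18 to 0.13 ± 0.143, and these 3 calls ended too. The call of CRR21 also ended with the pair number as a block (adjusted p = 0.0849). Leaving out 1 replicate ended 6 of the 10 calls in the group: AT3G22150 without PSII_DCMU replicate 1 or 3 (adjusted p = 0.0574 and 0.0549), AT1G79080 without PSI replicate 2 or any PSII_DCMU replicate (0.0674 to 0.101), AT3G26630 without PSI replicate 1 or 2 or PSII_DCMU replicate 1 or 3 (0.0542 to 0.078), AT3G51320 without PSI replicate 1 or 3 or PSII_DCMU replicate 1 or 2 (0.0537 to 0.0764), AT5G15280 without PSII_DCMU replicate 1 (0.05 after rounding) and CRR21 without any replicate except PSI replicate 2 (0.0721 to 0.102). Of 8 genes of the mTERF family, which bind nucleic acids in organelles, MTERF9 (0.90 ± 0.116) and AT4G09620 (0.91 ± 0.184) rose, AT3G46950 (-0.91 ± 0.119) and AT1G79220 (-0.32 ± 0.09) fell, and 4 did not pass, with the same counts when adjusted over the list alone (camera, adjusted p = 0.792, and 0.812 with an estimated correlation). The 4 were AT1G61990 (0.51), AT1G62010 (0.24), AT1G62150 (-0.24) and AT3G18870 (0.45), and the first 2 passed with place taken out (0.84 and 0.50). MTERF9 stood at 0.48 ± 0.122 and AT1G79220 at -0.11 ± 0.119 with place taken out, and only the latter lost its call. AT1G79220 also did not pass when any replicate except PSI replicate 2 was left out (adjusted p = 0.0808 to 0.111). Of 6 measured genes for plastid ribosomal proteins, from an earlier list of 39, PRPL5 rose by 0.79 ± 0.183, PRPL17 fell by 0.65 ± 0.175 and 4 did not pass, likewise when adjusted over the list alone, and the set test gave an adjusted p of 0.776. The 4 were PRPL34 (0.26), PRPS6 (-0.45), PRPS10 (-0.16) and PRPL29, which was listed at 0 in all samples. PRPL34 passed in opposite directions without PSI replicate 3 (0.37, adjusted p = 0.0372) and with brightness taken out (-0.41). After quantile normalization PRPS6 (-0.96 ± 0.18) and PRPS10 (-0.59 ± 0.17) passed, as they did with place taken out (-1.3 ± 0.179 and -0.80 ± 0.138). PRPL5 lost its call after quantile normalization (0.49 ± 0.182) and without PSI replicate 3 or any PSII_DCMU replicate (adjusted p = 0.0558 to 0.072). PRPL17 lost its call with place taken out (-0.35 ± 0.151) and when any replicate except PSII_DCMU replicate 1 was left out (adjusted p = 0.0515 to 0.102).

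Plastid metabolism held further changes in both directions. Of 7 genes of plastid amino acid and sulfur metabolism, 1 rose and 3 fell, with the same counts when adjusted over the list alone. DHAD, the dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose from 0.383 ± 0.0918 to 1.39 ± 0.0653 (SD, n = 3; log2 change 1.90 ± 0.199, adjusted p = 0.00225), or by 1.19 ± 0.136 with place taken out. The 3 that did not pass were KARI, APS4 (-0.05, but -0.49 and past the threshold after quantile normalization, and -0.27 with each array centred on its median) and ASL (-0.18). KARI, which acts in the step before it, stood at 0.02 ± 0.099 and passed in opposite directions after quantile normalization (-0.31 ± 0.092) and with place taken out (0.38 ± 0.137). HISN4 of histidine synthesis fell by 0.93 ± 0.086, or by 0.60 ± 0.113 with place taken out, CBL of methionine synthesis by 1.13 ± 0.309 and SIRB of siroheme synthesis by 0.37 ± 0.079. The call of CBL ended when any replicate except PSI replicate 3 was left out (adjusted p = 0.0552 to 0.102). That of SIRB ended without PSII_DCMU replicate 1 or 3 (0.0621 and 0.0622), with the pair number as a block, and with place taken out (-0.31 ± 0.121), while after quantile normalization its change was -0.70 ± 0.098. The set test of the group gave an adjusted p of 0.673, and 0.774 with an estimated correlation. Of 5 fibrillins, lipid-binding proteins of plastids, FBN5 rose by 1.87 ± 0.252, or by 1.09 ± 0.166 with place taken out, and the other 4, FBN10 (0.68, adjusted p = 0.0626), FBN6 (0.43), FBN8 (-0.42) and FBN2 (0.03), did not pass (1 rose when adjusted over the list alone; set test, adjusted p = 0.673, and 0.774 with an estimated correlation). FBN8 passed with each array centred on its median (-0.64) and without PSI replicate 2 (-0.53, adjusted p = 0.0418), and FBN10 without PSI replicate 1 (0.44, adjusted p = 0.0234). With place taken out FBN8 stood at -0.01, FBN10 at 0.03 and FBN6 at -0.24, none of them past the threshold, and after quantile normalization FBN8 stood at -0.17. In chlorophyll synthesis the methyltransferase gene CHLM differed by 0.21 ± 0.057 (adjusted p = 0.0345), and CHLP (-0.19, adjusted p = 0.223) did not pass, except with each array centred on its median (-0.41 ± 0.116), and stood at 0.11 ± 0.116 with place taken out. The call of CHLM ended with the pair number as a block, with each array centred on its median (-0.01 ± 0.049), and without PSI replicate 2 or any PSII_DCMU replicate (adjusted p = 0.0664 to 0.103), and with place taken out its change was 0.60 ± 0.109. FATB of fatty acid synthesis did not pass (-0.23, adjusted p = 0.554), except after quantile normalization (-0.79 ± 0.224) and with place and brightness taken out together (-0.59 ± 0.194).

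Outside the plastid, mitochondrial respiration, cell division, cell wall and developmental genes were measured in small groups. Of 5 mitochondrial respiration genes, AT5G47890, for a small complex I subunit, rose by 0.87 ± 0.102, while AT4G02580 and GLDH, which makes ascorbate at the mitochondrial inner membrane, fell (GLDH by 0.70 ± 0.064), and AT5G47030 (-0.01) and ETFQO (0.43) did not pass. AT5G47030 passed after quantile normalization (-0.56), and ETFQO with place taken out (0.70) and without PSI replicate 3 (0.55, adjusted p = 0.0436). AT5G47890 stood at 0.41 ± 0.129 with place taken out, and with brightness taken out as well its call ended (0.32 ± 0.129). Of 7 histone H3 and kinesin genes, which are most active in dividing cells, the kinesin genes AT4G14330, AT3G44050 (0.80 ± 0.143) and AT2G37420 (0.38 ± 0.105) rose, the histone H3 genes AT1G09200 and AT1G13370 (-0.43 ± 0.117) fell, and AT3G20150 (0.04) and AT5G65360, which lay under the floor in both groups, did not pass. AT3G20150 passed after quantile normalization (-0.62) and with place taken out (-0.84). The group's median change was 0.04 and its mean 0.38. The rises of AT3G44050 and AT2G37420 did not pass after quantile normalization (0.36 ± 0.125 and 0.10 ± 0.093) or with place taken out (0.31 ± 0.126 and -0.04 ± 0.12), where AT1G13370 stood at -0.98 ± 0.134. The call of AT2G37420 ended without PSI replicate 2 or 3 or PSII_DCMU replicate 1 or 3 (adjusted p = 0.0881 to 0.105), and that of AT1G13370 with the pair number as a block and when any replicate except PSI replicate 2 was left out (0.0599 to 0.0824). Of 4 endoglucanases of family GH9B, GH9B16 fell by 0.73 ± 0.174 and GH9B8 (-0.60), GH9B11 (-0.27) and GH9B12 (0) did not pass. GH9B8 and GH9B11 passed after quantile normalization (-1.09 and -0.26) and with each array centred on its median (-0.82 and -0.49), and GH9B8 also without PSI replicate 3 (-0.82, adjusted p = 0.0216). With place taken out they stood at -0.13 and 0.08. The call of GH9B16 ended without PSI replicate 1 or 3 or PSII_DCMU replicate 1 (adjusted p = 0.0548 to 0.068). Of 8 regulators of flower and shoot development, listed as markers of other organs, 2 rose and 3 fell. SPL, a regulator of sporogenesis, rose by 1.49 ± 0.352, and LAS, which acts in axillary meristems, fell by 0.80 ± 0.078, as did the MADS-box gene AGL54 by 0.51 ± 0.072. AGL103 rose by 0.60 ± 0.163 and AGL26 fell by 0.32 ± 0.072. TCP15 (-0.16), SAP (0.01) and IAA31, listed at 0 in all samples, did not pass, though TCP15 and SAP did with place taken out (-0.56 and -0.64) and SAP after quantile normalization (-0.60), and the median of the group was -0.08 while its mean was 0.04. SPL stood at 0.91 ± 0.223, LAS at -0.40 ± 0.125, AGL103 at 0.09 ± 0.132 and AGL26 at 0.14 ± 0.112 with place taken out, which ended the calls of AGL103 and AGL26. The call of LAS ended with brightness taken out as well (-0.25 ± 0.125), and the change of AGL54 after quantile normalization was -0.90 ± 0.049. The call of SPL ended without PSI replicate 1 or any PSII_DCMU replicate (adjusted p = 0.0591 to 0.0783), that of AGL103 without PSI replicate 1 or 3 or PSII_DCMU replicate 1 or 3 (0.0723 to 0.0945) and with the pair number as a block, and that of AGL26 without PSII_DCMU replicate 1 or 2 (0.0683 and 0.0583). The counts in these 4 groups were the same when adjusted over the list alone, and no shift of any of the groups as a set was detected (camera, adjusted p = 0.747, 0.792, 0.628 and 0.673 in the order given, and 0.774 to 0.812 with an estimated correlation).

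**Figure D4:**
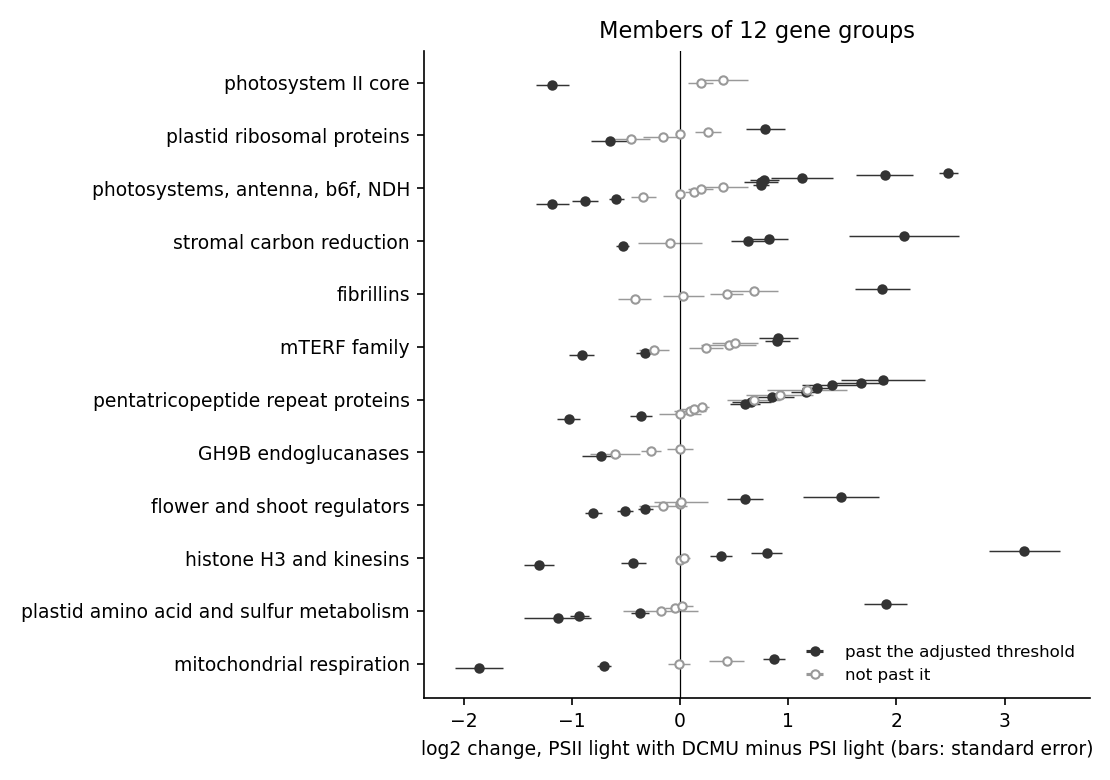
Log2 change of each measured member (points, with standard errors, n = 3 per group) of the 12 gene groups with at least 3 measured genes, filled where the adjusted p passed 0.05 and open where it did not. Most groups hold members on both sides of 0, and 14 of the 17 pentatricopeptide repeat genes lie above 0.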

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

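No test of an explanation was run here, and list members outside the rule for named genes were checked only after their values were seen. Among 234 sets of 6 samples (112 named features and 5 column summaries in each group), 4 stood out by the distance of a single sample from the others. Chance marks about 1 set in 20 under independence, and the paired samples are not independent. The antenna gene LHCB1.5 had an intensity of 9.80 in sample 4 under PSI light, against 12.5 to 14.1 in the other 5 samples of the group, a gap of 0.632 of the group's range. Its partner, sample 3, had 14.1, although partners were nearly alike across features.

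The other 3 lay under the floor of 0.0431, where an order of values carries no meaning. CCB3, of the cytochrome b6f assembly pathway, read 0.0242 in sample 1 under PSI light (gap 0.695 of the range) and 0.0106 in sample 5 under PSII light with DCMU, with the other 5 at 0 (gap 1). The histone H3 gene AT5G65360 read 0.0326 in sample 5 under PSI light and was listed at 0 in the other 5 (gap 1).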

How the results depend on the processing

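The tests with brightness, place or both taken out, with features never at the floor, with a block and random pairs together, and the permutation test over 12 samples were chosen after the data were seen. Against 1667 calls (909 higher, 758 lower), an adjusted p of 0.01 left 892 (505 and 387), and a 2-fold minimum left 668 (521 and 147), as stricter thresholds must. Under the other alternatives the count stayed within 1.5 times, for higher and lower calls alike, and leaving out 1 replicate gave 1138 to 1685. With the pair number as a block 1656 were called, 1480 of them among the 1667 in the same direction. The block also let AT1G31790, AT2G46050, GH9B8 and the feature of AT2G25870 with the negative change pass and ended the call of CRR21. Beyond these and the changes given with the genes, it changed no other call of a named gene or list. Calls shared in the same direction were 1352 after quantile normalization (2 opposite), 1477 with median centring and 1001 with place and brightness taken out (14 opposite).

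Of the 57 genes named by rule, 48 were called, and 33 of these kept call and direction under every alternative that gave a value. Of 55 features outside the rule 23 were called, and 7 kept it so. Signs changed as follows where the gene passed the test before or after, and the cause was not tested except for features under the floor; other genes changed sign without passing in either. After quantile normalization KARI stood at -0.31, AT3G51320 at -0.09, SAP at -0.60 and AT3G20150 at -0.62, and with median centring CHLM at -0.01. Brightness taken out brought PRPL34 to -0.41, AT3G51320 to -0.09 and AT3G20150 to -0.63. Place taken out brought PIFI to -0.03, OTP85 to -0.76, AT3G49740 to -0.69, SAP to -0.64, AGL26 to 0.14, AT2G37420 to -0.04 and AT3G20150 to -0.84. It moved PRPL29 (-0.46), CCB3 (-0.62) and AT5G65360 (-0.54) too, which lie under the floor, so these values come from the correction alone. Place and brightness together brought PIFI to -0.27, OTP85 to -1.01, AT3G49740 to -0.59, AT3G51320 to -0.11, SAP to -0.90, AGL26 to 0.17, AT2G37420 to -0.12 and AT3G20150 to -1.03.

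No camera call changed, while fry, which does not compare a list with other genes, passed 8 of the 10 added lists, the pentatricopeptide repeat list with adjusted p = 0.00756 (with camera 0.0517 to 0.352 over the alternatives at the preset correlation and 0.774 with an estimated one). An exact test of 3 against 3 was not run, since it cannot pass, and no gene named by rule had another feature paired with it alone. Features paired with several genes were not searched. Intensities near the floor limit the folds of the dimmest genes.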

Other observations

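The tests with place or with place and brightness taken out, with lists matched on brightness and with random draws were chosen after the results were seen, as was what the planned quantile normalization and the correlation by number were taken to decide, and the removal of a brightness trend was added after the data were seen, with its prediction written before its own result. Of 2 features that the gene table assigns to AT2G25870, 1 rose from 0.321 ± 0.0229 to 0.782 ± 0.0756 (SD, n = 3; 1.31 ± 0.093, adjusted p = 0.000887) and the other went from 1.58 ± 0.222 to 1.07 ± 0.20 (-0.56 ± 0.186, adjusted p = 0.0608). It was the only gene with more than 1 feature of its own. With place taken out the changes were 1.44 and -0.49, both past the threshold. The fall also passed with the pair number as a block, but not after quantile normalization (-0.42, limma, adjusted p = 0.114). Whether the features of 1 gene model moved apart is therefore uncertain.

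The broadest pattern was that 1667 of 3439 features were called. Only 10 splits of the 6 replicates exist, too few for a share under 0.05, and 1 split, the real one, reached 1667, while the highest other called 0. After quantile normalization 81.1% of calls were kept in direction, and after a brightness trend was taken out 74.9%. This argues against a difference in scale or brightness between the arrays as the whole cause. With place taken out 64.8% were kept, and with place and brightness taken out 60.0%. The correction took out 1 pattern shared by all runs, so a place effect that differs between runs would remain. These shares therefore cannot exclude place. The correction for place alone called 133 of the 141 features under the floor, so its share is less certain. With brightness taken out as well, 2 of them were called. Blocks of 4 times 96 feature numbers explained 2.41% of the variance, but such a block is longer than the run of 3 times 96 that the changes follow. Blocks of 96 feature numbers explained 18.9%, against a median of 1.35% in random orders. Place may account for part of the calls, and how large a part stays open. No label gives a batch. The joint deviation of same-numbered replicates (correlation at least 0.29) shows a factor shared across the groups. These deviations were taken from each group's mean, so they cannot show a batch that coincides with the group. Such a batch stays open as a cause of the calls.

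NDHS, NDHN, PIFI, CRR41 and CRR21, NDH-related genes grouped after their values were seen because they rose, did so by 0.66 to 1.89 with a median of 0.75. The grouping is not a full list, and measured genes that act on the NDH complex without rising may be left out. A hypothesis is that the light, DCMU or both, which the design cannot tell apart, act on genes of the NDH complex. This complex feeds electrons to plastoquinone from the stroma. The hypothesis would need these genes to stand apart from features of like brightness. The tables do not set them apart: their median lay at percentile 88.7 of 10000 random lists matched on brightness, and with place taken out 2 of the 5, NDHS and CRR41, were called higher, the median was 0.13 and the percentile 65.6. CRR21 then stood at 0.13 ± 0.143, and its call also ended with the pair number as a block (adjusted p = 0.0849) and when any replicate except PSI replicate 2 was left out (0.0721 to 0.102). Brightness and place remain candidate explanations, and the 0.19% of draws of 5 named features in which all rose decides nothing for genes grouped because they rose.

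Genes for pentatricopeptide repeat proteins had a median change of 0.68, at percentile 99.3 of 10000 random lists matched on brightness. With place taken out their median was 0.51, at percentile 99.7. Both percentiles were high, although the genes called were in part others. The list was picked for these comparisons after its values were seen, so they cannot set brightness or place aside. Chance remains open, since this was 1 of 12 lists and its set test had an adjusted p of 0.251. A shift of pentatricopeptide repeat genes under PSII light with DCMU may be followed up as a hypothesis, and the median stayed between 0.46 and 0.82 over 23 alternatives. The values that raised the hypothesis cannot decide it, and other samples would be needed.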
